A study of Mus musculus with 6 samples.

How the data were processed

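The series holds RNA sequencing of isolated pancreatic islets from mice, with 3 libraries labelled control and 3 labelled as a β cell-specific Dhps knockout. Per the labels' protocols, total RNA was extracted with a micro-scale column kit, 10 ng per sample was copied into cDNA with poly-dT priming and the SMART-Seq v4 low-input chemistry, the cDNA was sheared by sonication, and barcoded Ion Plus Fragment libraries were made. Poly-dT priming selects polyadenylated RNA, amplification from low input adds noise to rare transcripts, and this kind of shearing keeps no record of strand. The submitters' processing notes name STAR 2.4.2a, featureCounts, Subread 1.5.0, edgeR and the mouse build mm10. The annotation used and the strand and multi-mapping settings of the counting are not given in the sources used here.

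The deposited table gives whole-number counts per gene for each library, not normalized, with the exon coordinates and the summed exon length of each gene, per the file headers. The gene length column of the deposited table, in another unit (bp), was used only to describe Dhps. The table lists 24421 genes, of which 6405 had no count in any library. There were 27 identifiers that read as calendar dates, a known effect of spreadsheet software on symbols of the Mar, Sep and Dec families, and 4 rows shared such an identifier with another row; these stayed in the fit and are not named. Columns were matched to samples by name, and the totals of 21027737 to 23249895 counts per library are sums over the listed genes. Genes whose exons overlap another gene, near-identical families and antisense partners cannot be separated by these counts. Overlaps are marked in the text where the other gene had a mean of 17 or more counts; for the 7 other named genes with an overlap that mean was 9.67 or less. Overlaps were found with GenomicRanges 1.54.1, ignoring strand.

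The groups, the tests, 29 gene lists, the rule for naming genes and most alternatives were set before the data were examined. Computations used R 4.3.3. Counts were tested in edgeR 4.0.16 with TMM factors, edgeR's default expression filter by group, quasi-likelihood fits and a design with group as the only term; 13736 genes passed the filter. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over all genes tested, with a threshold of 0.05. Standard errors were derived from the fold change and the quasi-likelihood F value. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. Values for Tph1 include a ratio of summed, TMM-scaled counts with an exact 95% binomial interval, which covers counting error only.

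Gene lists with at least 4 tested members (28 of 29) were compared with all other genes by camera (limma 3.58.1) on log2 CPM with the preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. This test called 20 lists. With the correlation estimated per list it called 0, and fry, which tests whether a list moves on balance without comparing it with other genes, called 8. Counts of members are given over all genes tested and adjusted over the list alone. A pair of lists shared each of the genes Cdkn1a, Ddit3, Eif5a, Eif5a2, Gdf15 and Pdgfra. Shares of counts were compared with exact two-sided permutation tests, whose smallest possible p is 0.1 with 3 against 3 libraries; 95% intervals of shares are Wilson intervals.

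Named genes were Dhps, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, passing over predicted genes. From each list, up to 4 called members with the smallest p were added. A fixed set was also named whatever the p, which made 104 genes in all. It held hormones, cyclins, polyamine and lactogen genes, the proliferation markers Mki67 and Top2a, and the β cell genes Mafa, Pdx1 and Ucn3. Others are said to be named after their values were seen. Some genes that the rule names are not reported here.

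Pairs of libraries within a group differed by more than counting noise, with chi-square values per degree of freedom of 10.8 or more, so no library was counted as a repeat deposit of another. This does not show that the libraries come from separate animals. The procedure was tested on simulated data drawn from the same means, dispersions and library sizes with 200 changed genes among 13736. It recovered 36% of genes changed 1.5-fold, 76% of those changed 2-fold, 90% at 4-fold and 100% at 8-fold, and 9 of 160 calls were false. Each gene was drawn independently, so these shares may not carry over to genes that vary together. Changes under 2-fold can therefore be missed at this depth and number of libraries.

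The alternatives were RLE and upper-quartile factors, no expression filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, removal of acinar and hormone genes, and leaving out each library in turn. Adding each library's acinar or myeloid score (the mean log2 CPM of that list) as a covariate was chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.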

Results

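RNA was sequenced from isolated mouse pancreatic islets, the clusters of hormone-secreting cells that hold the insulin-producing β cells. The 6 libraries comprised 3 controls and 3 labelled as a β cell-specific knockout of Dhps on a C57BL/6J background. Dhps encodes deoxyhypusine synthase, the enzyme that uses the polyamine spermidine to start the hypusine modification of the translation factor eIF5A. The knockout label combined a floxed Dhps allele with MIP1-CreERT, a tamoxifen-inducible Cre recombinase driven by the mouse insulin promoter. Whether the controls carried Cre was not given in the labels, and the prefix HF in the sample names was not spelled out there. The series title placed the comparison in the question of how hypusine and polyamine metabolism in β cells relates to adaptive β cell proliferation. Each library held between 21027737 and 23249895 counts assigned to genes, with between 15954 and 16370 genes detected. The labels did not say that the replicates came from separate animals, so p-values measure only the spread between these samples.

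Dhps itself was compared first, because the targeted gene checks the labels. It was not called different: 12.6 ± 0.704 CPM (counts scaled to library size) in the controls and 11.96 ± 0.689 CPM in the knockout-labelled libraries (SD, n = 3 each). The log2 fold change was −0.07 ± 0.12 (SE), with a 95% interval from −0.34 to 0.20 and an adjusted p of 0.742. An exact two-sided permutation test gave p = 0.4, where 0.1 is the smallest value that 3 against 3 libraries allow. Between 225 and 321 counts fell on Dhps in each library. The gene lies on chromosome 8 from 85071757 to 85075161 (mm10), and its count summed all 9 exons, a model of 1332 bp that overlaps exons of Wdr83. The counts therefore could not separate transcripts that lack part of the gene, reads from islet cells other than β cells, or reads from Wdr83. Because Dhps counts did not separate the groups, directions below refer to libraries labelled knockout.

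**Figure D1:**
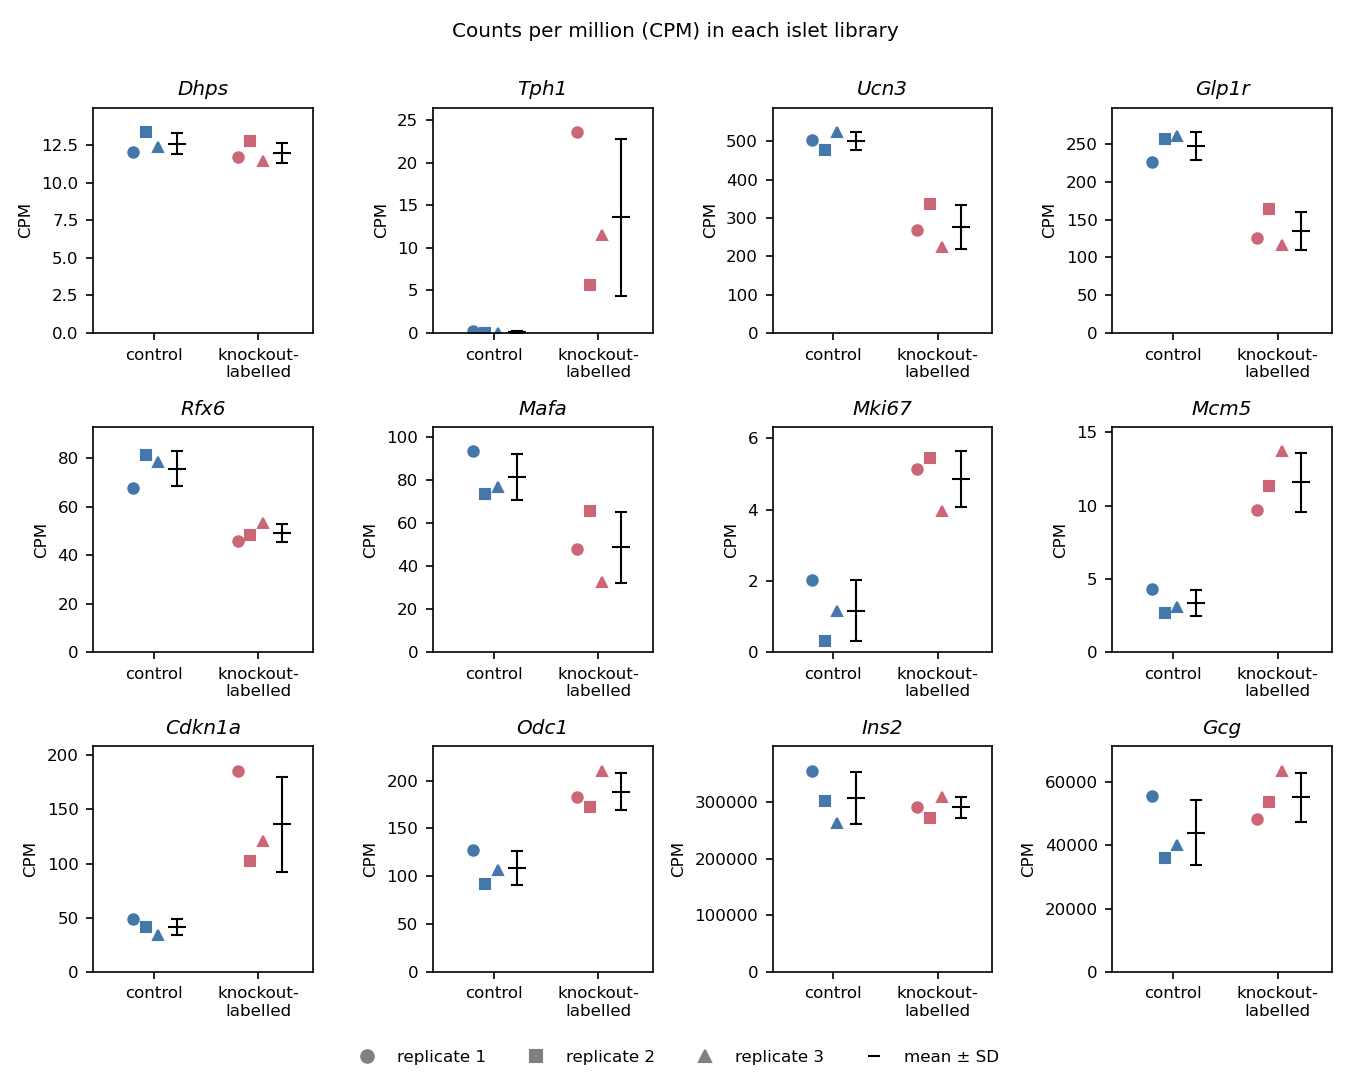
Expression (CPM, linear axes from 0) of 12 genes in each of the 3 control (blue) and 3 knockout-labelled (red) libraries; marker shapes give the replicate number and bars the mean ± SD. Dhps overlapped between groups, Tph1 was near 0 in the controls and 13.6 ± 9.18 CPM in the knockout-labelled libraries, and Ucn3, Glp1r and Rfx6 lay below every control.

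The islets labelled knockout differed widely from the controls. Among 13736 tested genes, 568 rose and 361 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and in each of these 929 genes the 3 libraries of each label did not overlap the other 3. At least 2-fold changes were far more frequent upward, with 332 genes against 47 downward. Without adjustment, 3642 genes had a p under 0.05. Non-overlapping groups were seen for 32.1% of tested genes, where the chance for any single gene is 10%. Genes that vary together can separate together, so this excess does not argue against chance. The count of 929 depended on single libraries: it was 113 without control 2, 234 without control 3, 60 without knockout-labelled replicate 1 and 348 without replicate 3, against 1028 without control 1 and 715 without knockout-labelled replicate 2. With each library's acinar score as a covariate, chosen after the data were seen, edgeR called 0 genes, with 1453 at an unadjusted p under 0.05, and with a myeloid score it called 2, with 1873 at that level.

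Tph1, which encodes the rate-limiting enzyme of peripheral serotonin synthesis, showed the largest rise among the genes eligible for naming. It had 5, 0 and 1 counts in the controls and 537, 120 and 226 in the knockout-labelled libraries, a ratio of 164 (95% counting interval 74.9 to 448). Its fitted log2 fold change was 7.23 ± 0.78 (SE, adjusted p = 0.00543). Esr1, the estrogen receptor α, rose by 4.05 ± 0.65 on the log2 scale. Its counts were 7, 5 and 22 in the controls and 339, 119 and 65 in the knockout-labelled libraries. Counts per gene could not separate Esr1 from any estrogen receptor sequence in the CreERT transgene, which was not tested. C1qtnf1, a secreted C1q and TNF related protein, rose by 2.86 ± 0.74. This mean was carried largely by knockout-labelled replicate 3, with 843 counts against 119 and 126 in replicates 1 and 2. The endothelial adhesion molecules Sele (2.55 ± 0.26) and Selp (2.42 ± 0.40) rose, as did Mmp2, a matrix metalloproteinase (2.53 ± 0.48), Rac2, a GTPase of blood cells (2.38 ± 0.62, with 2.16 CPM in knockout-labelled replicate 1, 16.4 in replicate 2 and 2.04 in control 1), C3, the central complement component (2.23 ± 0.30), Crispld2 (2.17 ± 0.39) and Spink1, a trypsin inhibitor of acinar cells (2.14 ± 0.54).

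The 10 largest falls among the genes eligible for naming included channel genes and activity-induced genes. The voltage-gated potassium channel subunit Kcnf1 fell from 10.04 ± 1.59 to 1.76 ± 0.594 CPM (log2 fold change −2.50 ± 0.26, adjusted p = 0.00543). Trpm5, a calcium-activated cation channel of β cells, fell from 106 ± 20.5 to 35.3 ± 23.8 CPM (−1.59 ± 0.40). The activity-induced genes Arc (−1.81 ± 0.35), Egr4 (−1.90 ± 0.39), Npas4 (−1.67 ± 0.31) and Fos (−1.63 ± 0.42) also fell. The remaining 4 were Rasd1, a Ras-related GTPase (−2.17 ± 0.40, with exons overlapping Med9), Col6a6, a collagen chain (−1.97 ± 0.45), T2 (−1.81 ± 0.38, overlapping Gm16702) and Anks4b (−1.52 ± 0.24).

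**Figure D2:**
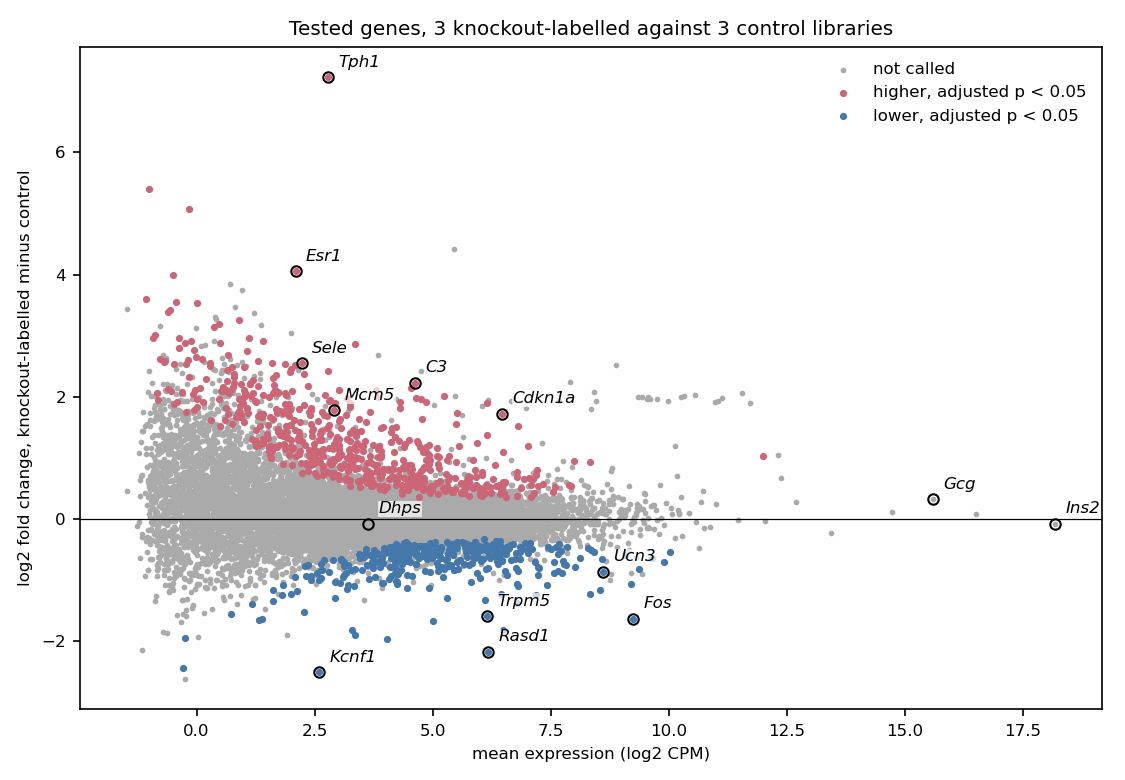
Log2 fold change (knockout-labelled minus control) against mean expression (log2 CPM) for the 13736 tested genes; red points rose and blue points fell at an adjusted p under 0.05, and grey points were not called. Tph1 stands apart at 7.23, Dhps lies at −0.07 and Ins2, the most abundant transcript, at −0.08.

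The share of acinar transcripts was higher in each of the 3 knockout-labelled libraries than in each control. Shares of counts do not measure cell numbers. Digestive enzyme genes of the acinar list took 0.949% ± 0.698 of counts in the controls and 3.70% ± 0.190 in the knockout-labelled libraries (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). Control 3 held only 0.144% (95% Wilson interval 0.143 to 0.146), against 1.38% (1.37 to 1.38) and 1.33% (1.32 to 1.33) in controls 1 and 2. Intervals cover counting error only and treat each read as independent. These reads carry no molecular identifiers to mark amplification copies, so the intervals may be too narrow. The 6 islet hormone genes Ins1, Ins2, Gcg, Sst, Ppy and Iapp together took 48.2% ± 3.50 and 47.4% ± 0.939 of counts (exact permutation p = 0.8), and the share of counts of these hormone genes differed by 1.01 percentage points in the opposite direction without control 1. The 10 most abundant genes took 50.7% ± 3.33 in the controls, with a difference between groups of −0.737 percentage points (exact permutation p = 0.8).

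**Figure D3:**
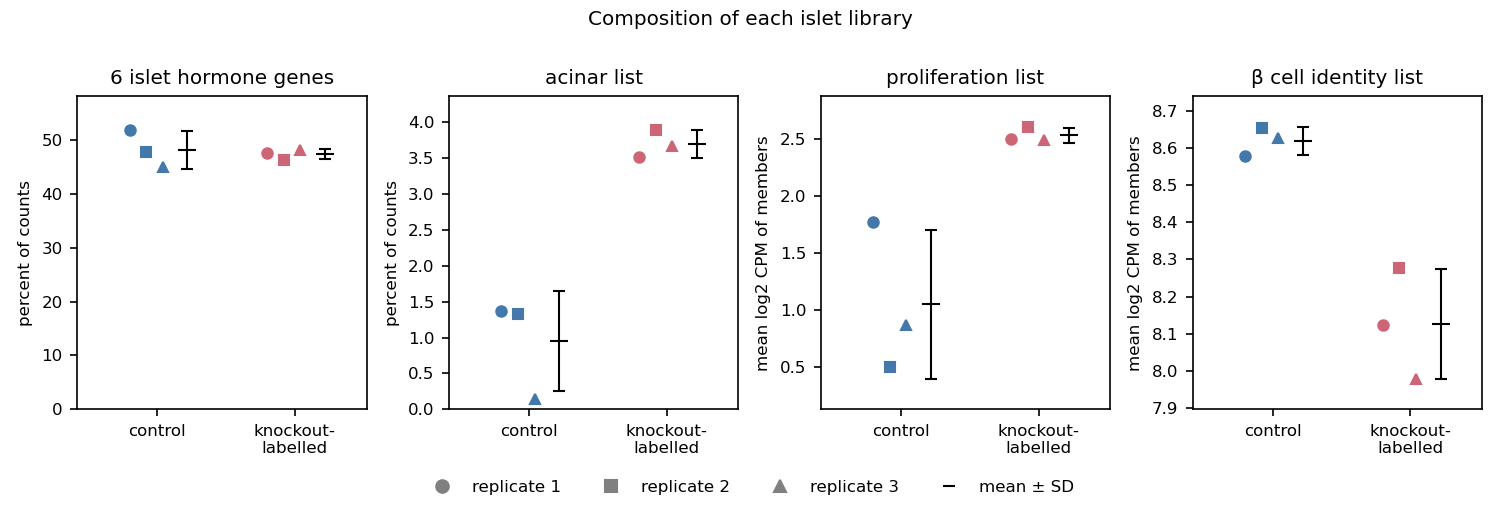
Composition of each library: percent of counts in the 6 hormone genes and in the acinar list (axes from 0), and mean log2 CPM over the members of the proliferation and β cell identity lists (axes not from 0), with 3 control (blue) and 3 knockout-labelled (red) libraries and bars for mean ± SD. Knockout-labelled libraries held 3.52% to 3.90% acinar counts against 0.144% to 1.38% in the controls, while the hormone share overlapped.

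Markers of non-β cells were mostly higher in the knockout-labelled libraries. Of 30 tested acinar genes, 1 rose over all genes, Amy1 (2.10 ± 0.36), and 28 rose when adjusted over the list alone. Their median log2 fold change was 1.96, or 1.43 without control 3 (camera adjusted p = 4.11e-09, but adjusted p = 0.463 with an estimated correlation). Trypsin, elastase and amylase genes are near-identical families, so single members are uncertain. Among 16 stellate cell and fibroblast genes, 5 rose, 0 fell and 11 were not called (9 rose adjusted over the list alone). The proteoglycans Dcn (1.97 ± 0.22) and Lum (1.95 ± 0.26), the matrix protein Mgp (1.20 ± 0.16) and the growth factor receptor Pdgfra (2.68 ± 0.41) were among them (list median 0.97, camera adjusted p = 7.78e-07, adjusted p = 0.368 with an estimated correlation). The stellate median was 0.61 without control 1, 1.64 without control 3, 2.11 with the acinar covariate, and 0.25 with the myeloid covariate, which ended its call (camera adjusted p = 0.292). Of 17 macrophage and myeloid genes, 6 rose, 0 fell and 11 were not called (12 rose adjusted over the list alone). Examples were the lysosomal glycoprotein Cd68 (1.98 ± 0.22), lysozyme Lyz2 (1.73 ± 0.29), Laptm5 (1.21 ± 0.20) and C1qc (1.10 ± 0.15), with a median of 0.82 (camera adjusted p = 6.12e-07, adjusted p = 0.276 with an estimated correlation).

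Vascular, duct and lymphocyte markers moved the same way. Endothelial genes rose for 5 of 15, fell for 0 and were not called for 10 (8 rose adjusted over the list alone), including the adhesion molecule Pecam1 (0.74 ± 0.11), von Willebrand factor Vwf (1.70 ± 0.26), the angiopoietin receptor Tek (0.54 ± 0.13) and Eng (0.54 ± 0.11, overlapping Fpgs). Their median was 0.36 (camera adjusted p = 0.000218, 0.283 with the myeloid covariate at a median of 0.44, and adjusted p = 0.463 with an estimated correlation). Of 10 duct genes, Clu (0.94 ± 0.18) and Spp1 (1.53 ± 0.35), both secreted glycoproteins, rose and 8 were not called (3 rose adjusted over the list alone). The duct median was 0.81 (camera adjusted p = 0.0182, 0.0657 without knockout-labelled replicate 1, and adjusted p = 0.463 with an estimated correlation), 0.09 with the acinar covariate (camera adjusted p = 0.826) and 1.14 with the myeloid covariate (0.283). Among 11 lymphocyte genes the T cell coreceptor Cd4 rose (2.96 ± 0.72), 10 were not called, and 6 rose adjusted over the list alone. The lymphocyte median was 2.62 (camera adjusted p = 0.00345, adjusted p = 0.463 with an estimated correlation), or 1.33 without knockout-labelled replicate 2, where the camera adjusted p was 0.0526, 0.57 with the acinar covariate (camera adjusted p = 0.175) and −0.49 with the myeloid covariate (0.401). That library had the highest mean log2 CPM over the lymphocyte genes of the 6, and the other 5 lay between −1.71 and 0.72. None of 7 Schwann cell genes was called, over all genes or adjusted over the list alone (median 0.56, camera adjusted p = 0.0545). The Schwann cell list was called without control 2 (median 0.74, camera adjusted p = 0.0289), without knockout-labelled replicate 3 (0.84, 0.0166) and with a replicate block (0.59, 0.043). Its median was 0.33 without control 3, 0.03 with the acinar covariate (camera adjusted p = 0.342) and 0.22 with the myeloid covariate (0.598).

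Of the non-β endocrine markers, some delta, PP and epsilon cell genes rose and alpha cell genes were not called. Glucagon (Gcg) counts were 43991 ± 10334 CPM in the controls and 55189 ± 7753 CPM in the knockout-labelled libraries (log2 fold change 0.33 ± 0.24, adjusted p = 0.414). None of the 9 alpha cell genes was called over all genes, and 1 rose adjusted over the list alone (median 0.30, camera adjusted p = 0.0545). The alpha cell list was called without control 1 (camera adjusted p = 0.0199) and without knockout-labelled replicates 1 (0.0332) or 2 (0.045). It was also called with no filter on low counts (0.0396) and with the myeloid covariate (median 0.69, 0.0053). With the acinar covariate it was not called (median 0.16, camera adjusted p = 0.846). Its median was 0.16 without control 3 and 0.15 without knockout-labelled replicate 3. Of 7 delta, PP and epsilon cell genes, the transcription factor Hhex (0.50 ± 0.11) and the peptide Pyy (1.03 ± 0.25) rose and 5 were not called (4 rose adjusted over the list alone). Somatostatin (Sst, 0.68 ± 0.20, adjusted p = 0.0654) and pancreatic polypeptide (Ppy, 1.05 ± 0.55, adjusted p = 0.253) did not pass. This list's median was 0.64 (camera adjusted p = 0.0182, 0.0527 without control 1, 0.0539 with the acinar covariate, and adjusted p = 0.276 with an estimated correlation), and 1.17 with the myeloid covariate (camera adjusted p = 0.0641).

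Many genes of β cell identity and function were lower in the knockout-labelled libraries, while the insulin transcripts and several other abundant members were not. Of 26 tested members, 10 fell, 0 rose and 16 were not called, and 18 fell when adjusted over the list alone. Glp1r, the receptor for the incretin GLP-1, fell from 248 ± 18.4 to 135 ± 25.3 CPM (log2 fold change −0.88 ± 0.14, adjusted p = 0.0146). Urocortin 3 (Ucn3), a marker of mature β cells, fell from 502 ± 23.2 to 276 ± 56.6 CPM (−0.86 ± 0.15, adjusted p = 0.0197). The endocrine transcription factors Rfx6 (−0.62 ± 0.11) and Pax6 (−0.66 ± 0.12, overlapping Elp4) and the channel Trpm5 also fell. The other 5 that fell, named after their values were seen, were the glucose transporter Slc2a2 (−1.15 ± 0.24), the granule zinc transporter Slc30a8 (−0.81 ± 0.17) and the transcription factors Isl1 (−0.67 ± 0.12), Nkx6-1 (−0.65 ± 0.12) and Neurod1 (−0.52 ± 0.12). Mafa (−0.74 ± 0.21, adjusted p = 0.0625) and Pdx1 (−0.54 ± 0.19, adjusted p = 0.114) did not pass. Ins1 (0.09 ± 0.22, adjusted p = 0.838) and Ins2 (−0.08 ± 0.25, adjusted p = 0.875), which are close paralogs, were not called. Neither were Iapp (0.12 ± 0.21), Pcsk1 (0.06 ± 0.19), Pcsk2 (−0.02 ± 0.16), G6pc2 (−0.04 ± 0.17), Abcc8 (−0.09 ± 0.15) and Ero1lb (−0.14 ± 0.19), named after their values were seen. Of the 26 members, 23 had a negative log2 fold change and 3 a positive one. The list's median log2 fold change was −0.47 (camera adjusted p = 2.25e-07), which did not hold with an estimated correlation (adjusted p = 0.276), and −0.91 with the myeloid covariate. The same libraries held more acinar, stromal and myeloid transcripts, as given above.

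Secretory genes and genes that β cells normally keep low moved in opposite directions. Of 23 exocytosis genes, 4 fell, 0 rose and 19 were not called (6 fell adjusted over the list alone). Among them were the granule-docking effector Sytl4 (−0.84 ± 0.18), the calcium channel subunit Cacnb2 (−0.46 ± 0.11) and Rph3al (−0.43 ± 0.11), with a list median of −0.23 (camera adjusted p = 0.00381, 0.292 with the myeloid covariate at a median of −0.23, and adjusted p = 0.276 with an estimated correlation), and −0.11 with the acinar covariate. Of 19 genes normally low in β cells, 10 rose, 0 fell and 9 were not called (16 rose adjusted over the list alone). Among them were catalase Cat (from 4.90 ± 0.138 to 10.9 ± 0.441 CPM, log2 fold change 1.16 ± 0.14), the lactate transporter Slc16a1 (1.54 ± 0.25), Igfbp4 (1.28 ± 0.20) and Pdgfra. All 19 had a positive log2 fold change, with a median of 1.28 (camera adjusted p = 8.63e-10, adjusted p = 0.103 with an estimated correlation). These genes are expressed by other islet and exocrine cells, whose markers were also higher, and Pdgfra stood in the stellate cell list too.

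Cell cycle genes were higher in the knockout-labelled libraries. Of 36 proliferation genes, 18 rose, 0 fell and 18 were not called, and 31 rose when adjusted over the list alone. The proliferation marker Mki67 rose from 1.17 ± 0.852 to 4.85 ± 0.787 CPM (log2 fold change 2.06 ± 0.48, adjusted p = 0.0363) and the DNA topoisomerase Top2a from 2.90 ± 2.12 to 11.0 ± 3.29 CPM (1.94 ± 0.43). The replication helicase subunits Mcm5 (1.78 ± 0.22) and Mcm6 (0.79 ± 0.13) and the ribonucleotide reductase subunits Rrm1 (0.83 ± 0.13) and Rrm2 (from 2.92 ± 0.352 to 8.86 ± 1.84 CPM) also rose. The list's median was 1.55 (camera adjusted p = 4.71e-15), which did not hold with an estimated correlation (adjusted p = 0.353), and 2.19 without control 1. Mki67 passed the threshold without control 1 and missed it without each of the other 5 libraries in turn, with adjusted p between 0.0674 and 0.104. Acinar, stromal and myeloid markers were higher in the same libraries, and with the acinar covariate the proliferation median was 0.98.

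Regulators of entry into the cycle did not move as a group. Of 17 G1 phase regulators, the cyclin-dependent kinase inhibitor Cdkn1a and the transcription factor Myc (0.92 ± 0.19) rose and 15 were not called, with the same count adjusted over the list alone (median 0.16, camera adjusted p = 0.0882). The G1 phase median was 0.45 with no filter on low counts and 0.45 with the myeloid covariate, and the list was called in neither. Cyclin D2 (Ccnd2), the main D-type cyclin of β cells, was at 631 ± 92.2 and 548 ± 40.2 CPM (log2 fold change −0.20 ± 0.14, 95% interval −0.52 to 0.11, adjusted p = 0.387). Cyclin D1 (Ccnd1) was at 53.9 ± 10.04 and 54.1 ± 16.2 CPM (0.01 ± 0.20, adjusted p = 0.989). Cdkn1a rose from 41.3 ± 7.03 to 136 ± 43.8 CPM (1.72 ± 0.21, adjusted p = 0.0072). It also belonged to the p53 target list, where 6 of 18 rose, 0 fell and 12 were not called (7 rose adjusted over the list alone). Others were Phlda3 (1.49 ± 0.22), Ccng1 (0.67 ± 0.11) and the pro-apoptotic Bbc3 (0.85 ± 0.21), with a list median of 0.59 (camera adjusted p = 0.000416, adjusted p = 0.276 with an estimated correlation).

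**Figure D4:**
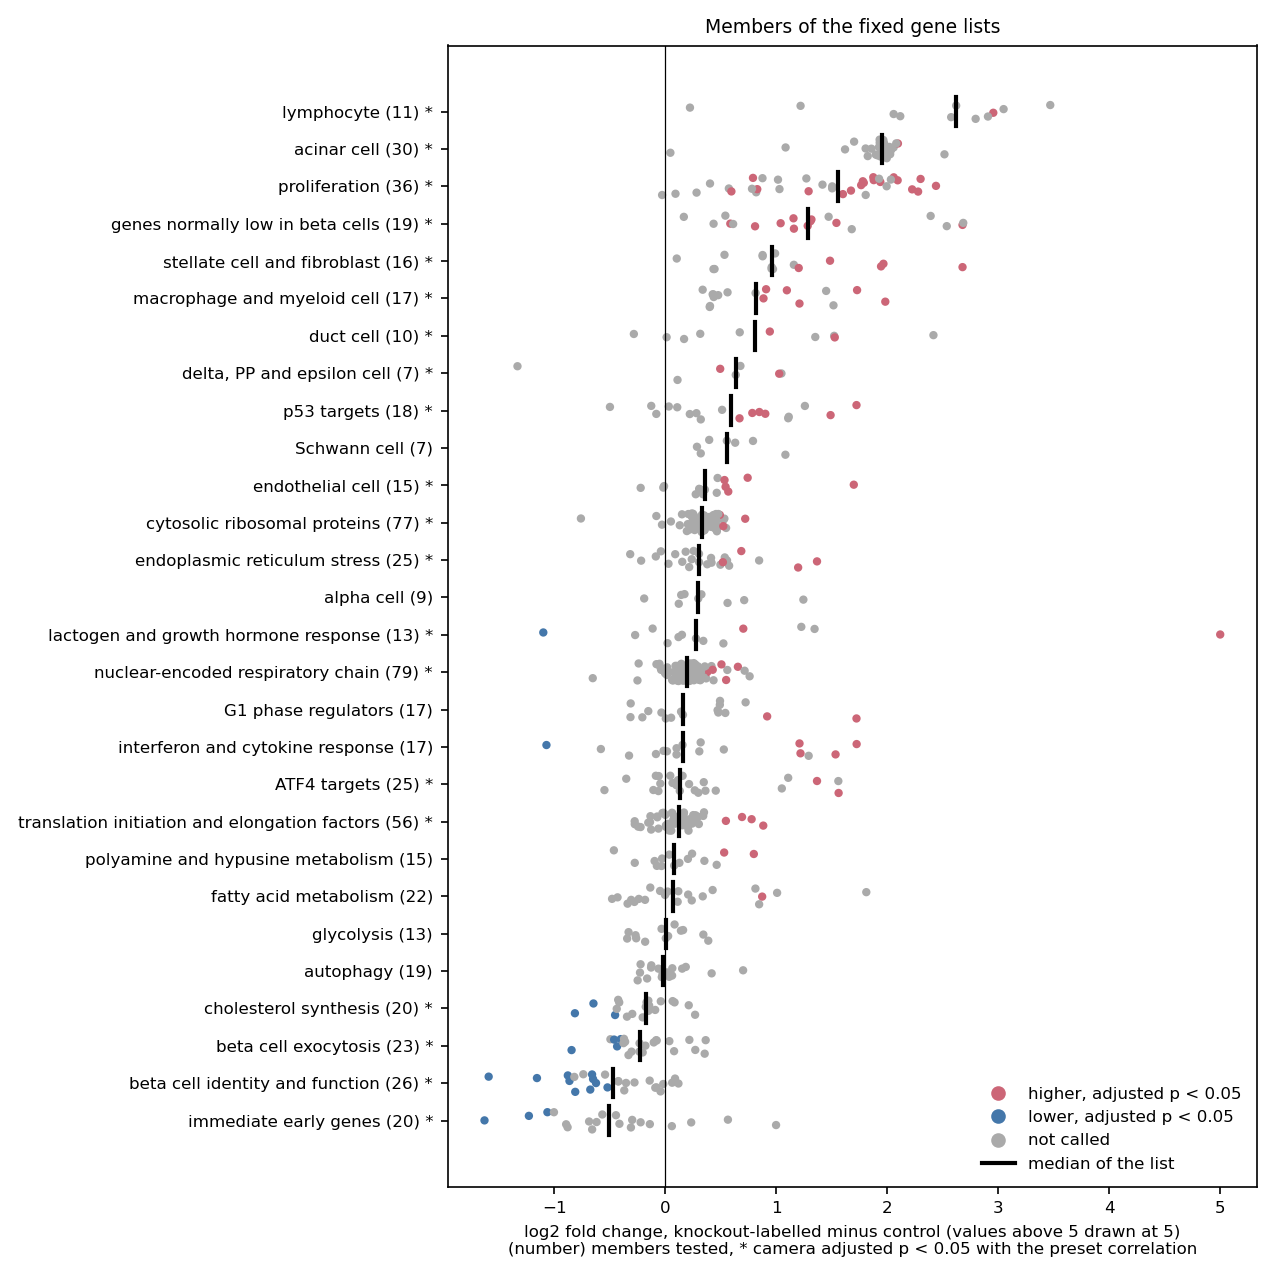
Log2 fold change (knockout-labelled minus control) of each tested member of 28 gene lists, with the number tested in parentheses; black bars are list medians, red and blue points passed an adjusted p under 0.05, and asterisks mark lists called by camera with its preset correlation. Medians ranged from −0.50 for immediate early genes to 2.62 for lymphocyte genes, and none of the lists was called with an estimated correlation.

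The polyamine and hypusine pathway showed limited changes. Of 15 tested genes, 2 rose, 0 fell and 13 were not called, with the same count adjusted over the list alone (median 0.08, camera adjusted p = 0.298). The polyamine median was 0.24 with the acinar covariate (camera adjusted p = 0.0706) and 0.16 with the myeloid covariate (0.598). Odc1, ornithine decarboxylase and the rate-limiting enzyme of polyamine synthesis, rose from 108 ± 17.8 to 189 ± 19.7 CPM (log2 fold change 0.80 ± 0.14, adjusted p = 0.0169). Sat1, which acetylates spermidine and spermine for their breakdown, rose from 20.8 ± 0.423 to 30.0 ± 2.24 CPM (0.53 ± 0.10, adjusted p = 0.0215). Eif5a, the protein that receives hypusine, had a log2 fold change of 0.24 ± 0.13 (adjusted p = 0.251), and Dohh, the enzyme that completes the modification, 0.21 ± 0.10 (adjusted p = 0.226). The 2 polyamine genes and the acinar, stromal and myeloid markers were higher in the same libraries.

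Transcripts of the translation and respiration machinery had modestly positive list medians, and camera with its preset correlation called their lists. None of them was called by fry (adjusted p 0.141 for ribosomal proteins, 0.113 for translation factors and 0.113 for the respiratory chain). Over all 13736 tested genes, 568 rose. Among 77 cytosolic ribosomal protein genes, 3 rose, 0 fell and 74 were not called (0 rose adjusted over the list alone). Rps27l (0.72 ± 0.15), a p53-induced relative of Rps27, was among those that passed. Their list had a median of 0.33 (camera adjusted p = 8.63e-10, adjusted p = 0.463 with an estimated correlation), 0.18 without control 3, and −0.02 with the acinar score as a covariate, which ended its call (camera adjusted p = 0.487), against 0.60 with the myeloid covariate. Of 56 translation factor genes, 4 rose, 0 fell and 52 were not called, with the same count adjusted over the list alone. The exchange factor subunit Eif2b5 (0.69 ± 0.11), Eif1ax (0.55 ± 0.12), the cap-binding repressor Eif4ebp1 (0.88 ± 0.20) and Eef1a2 (0.78 ± 0.20) were these 4, and the median was 0.13 (camera adjusted p = 0.0293, adjusted p = 0.464 with an estimated correlation). Without controls 2 or 3, or without knockout-labelled replicates 2 or 3, the camera adjusted p for translation factors lay between 0.0526 and 0.160. It was 0.0769 with no filter on low counts and 0.774 with the acinar covariate. The median for translation factors was 0.05 without control 3, −0.01 with the acinar covariate and 0.22 with the myeloid covariate. Nuclear-encoded respiratory chain genes rose for 5 of 79, fell for 0 and were not called for 74 (5 rose adjusted over the list alone). Atp5g1 (0.51 ± 0.11), Cox6a1 (0.55 ± 0.13), Ndufa13 (0.43 ± 0.10) and Uqcrq (0.66 ± 0.15) were examples, with a median of 0.20 (camera adjusted p = 1.95e-05, adjusted p = 0.463 with an estimated correlation). The respiratory chain median was 0.12 without control 3 and 0.06 with the acinar covariate, which ended its call (camera adjusted p = 0.389), and 0.46 with the myeloid covariate. The list of mitochondrially encoded genes had 0 members in the table.

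Apart from Tph1, the called members of the lactogen and growth hormone response list went in opposite directions. Of its 13 genes, Tph1 and the matrix protein Matn2 (0.70 ± 0.10) rose, the cytokine signalling suppressor Socs3 fell (−1.10 ± 0.21), and 10 were not called (4 rose and 1 fell adjusted over the list alone). The prolactin receptor Prlr was at 170 ± 34.1 and 216 ± 34.4 CPM (0.34 ± 0.16, adjusted p = 0.209). Tph2, the neuronal form of the serotonin enzyme, was below 1 CPM on average in both groups (0.28 ± 0.41, adjusted p = 0.714). The list's median was 0.28 (camera adjusted p = 0.0414, adjusted p = 0.331 with an estimated correlation). Its camera adjusted p was 0.0872 without control 1, 0.0657 without knockout-labelled replicate 1, 0.0788 without replicate 2, 0.0539 with the acinar covariate, 0.0514 with no filter on low counts and 0.397 with the myeloid covariate, where the lactogen median was 0.57.

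Stress genes rose in part. Of 25 endoplasmic reticulum stress genes, 4 rose, 0 fell and 21 were not called (9 rose adjusted over the list alone). The pro-apoptotic factor Ddit3 rose from 39.5 ± 0.910 to 102 ± 35.2 CPM (1.37 ± 0.20, adjusted p = 0.0115), although its exons overlap Mars. The chaperones Creld2 (1.20 ± 0.28) and Dnajb11 (0.69 ± 0.18) and the degradation factor Sel1l (0.52 ± 0.13) also rose, with a list median of 0.31 (camera adjusted p = 0.00142, adjusted p = 0.463 with an estimated correlation), and 0.77 with the myeloid covariate. Of 25 ATF4 targets, Ddit3 and the pseudokinase Trib3 (1.56 ± 0.24) rose, 0 fell and 23 were not called, with the same count adjusted over the list alone. The ATF4 median was 0.13 (camera adjusted p = 0.0351, adjusted p = 0.463 with an estimated correlation), and the camera adjusted p lay between 0.0526 and 0.110 without controls 2 or 3 or knockout-labelled replicates 1 or 2. The ATF4 median was 0.21 without knockout-labelled replicate 1 and 0.06 with the acinar covariate (camera adjusted p = 0.41), and the call also ended with the myeloid covariate (median 0.01, 0.306) and with no filter on low counts (0.0555).

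Immediate early genes, which respond within minutes to depolarisation or handling, were lower. Of 20 tested, Fos, Fosb (−1.06 ± 0.26) and Nr4a1 (−1.23 ± 0.28) fell and 17 were not called (6 fell and 2 rose adjusted over the list alone). The list's median was −0.50 (camera adjusted p = 0.00422, adjusted p = 0.465 with an estimated correlation, and fry adjusted p = 0.253). The immediate early median was −0.29 without knockout-labelled replicate 3, −1.53 with the myeloid covariate, and −0.24 with the acinar covariate, which ended its call (camera adjusted p = 0.115). Of 17 interferon and cytokine response genes, 4 rose and 1 fell, and 12 were not called (5 rose and 1 fell adjusted over the list alone). The chemokines Ccl2 (1.73 ± 0.31) and Cxcl1 (1.54 ± 0.31) and the GTPase Gbp2 (1.21 ± 0.30) rose, while the transcription factor Irf1 fell (−1.07 ± 0.25). Their median was 0.16 (camera adjusted p = 0.0608). The interferon list was called without control 3 (median 0.45, camera adjusted p = 0.00226), without knockout-labelled replicate 3 (0.24, 0.00531) and with the acinar covariate (0.64, 1.23e-05), and its median was 0.08 without control 1 and 0.02 without control 2.

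Among metabolic groups, cholesterol synthesis genes were lower by camera with its preset correlation, but fry did not call them (adjusted p = 0.0897). Of 20 tested, 3 fell, 0 rose and 17 were not called (6 fell adjusted over the list alone). The cholesterol carrier Stard4 (−0.65 ± 0.15) was among those that fell, with a list median of −0.17 (camera adjusted p = 0.00302, adjusted p = 0.368 with an estimated correlation). Of 22 fatty acid metabolism genes, the fatty acid carrier Fabp4 (0.87 ± 0.16) rose and 21 were not called (5 rose and 2 fell adjusted over the list alone, median 0.07, camera adjusted p = 0.791). None of 13 glycolysis genes was called over all genes, and 1 rose and 2 fell adjusted over the list alone. Their median was 0.01 and their mean −0.02, of opposite sign (camera adjusted p = 0.52). None of 19 autophagy genes was called either way (median −0.02, mean 0.02, camera adjusted p = 0.844), and this median was 0.01 with upper-quartile scaling.

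Calls of single genes depended on single libraries. Of 90 named genes that passed the threshold, 12 also passed with each of the 6 libraries left out in turn: Tph1, Sele, C3, Kcnf1, Cat, Dcn, Mgp, Lum, Cd68, Mcm5, Rrm2 and Cdkn1a. Calls among the named genes were lost for 68 without control 2, 49 without control 3 and 11 without control 1. Without knockout-labelled replicates 1, 2 and 3 the losses were 73, 19 and 36.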

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

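The acinar and myeloid covariate tests were chosen only after the data were seen, and the other alternatives were planned. Of 13736 tested genes, 929 were called with group as the only term. The number was 928 with RLE factors, 894 with upper-quartile factors, 918 with a filter of at least 1 CPM, 1037 without acinar and hormone genes, 891 with limma-voom and 826 with a replicate block. Replicate numbers did not pair the libraries (correlations of matched deviations −0.0371, −0.00688 and 0.0546). Genes called in both settings numbered 915, 847, 879, 928, 826 and 685. Upper-quartile factors made 68.8% of calls higher, against 61.1%.

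Without the expression filter 1413 genes were called, 620 of them lower, over 18016 tested genes. DESeq2 called 1658 (958 higher, 700 lower, 920 shared); the cause was not tested. The acinar covariate left 0 genes called by edgeR (0 higher, 0 lower, 1453 at an unadjusted p under 0.05) and the myeloid covariate 2 (0 higher, 2 lower, 1873 at that level). Over the 929 genes the median absolute log2 fold change went from 0.85 to 0.76 and 1.07, while the median SE grew from 0.17 to 0.26 and 0.42. Signs turned for 1 of these genes with the acinar covariate and for 24 with the myeloid covariate. Each score was higher in every knockout-labelled library than in every control, so these fits cannot separate the scores from the label. Leaving out each library in turn gave 60 to 1028 genes, 52 to 574 higher and 8 to 454 lower, with fewer samples.

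Of 104 named genes, 90 were called. Those that lost the call numbered 90 with the acinar covariate, 90 with the myeloid covariate, 12 with the block, 5 with limma-voom, 3 with DESeq2, 3 with upper-quartile factors and 2 with RLE factors. Signs turned for Ccnd1 (0.01): −0.0137 with no filter, −0.018 with the block, −0.20 with the acinar covariate, −0.0029 with DESeq2, −0.0144 with limma-voom, and −0.27 to 0.15 over left-out libraries. With the acinar covariate Ins1 turned to −0.15, and over left-out libraries it ranged from −0.0172 to 0.23. With the myeloid covariate Ins2 turned to 0.32, Rac2 to −0.47, Lyz2 to −0.22 and Laptm5 to −0.12. Over left-out libraries Ins2 ranged from −0.19 to 0.0414. Lyz2 and Laptm5 are members of the myeloid list, so that covariate takes up their change by construction; for the others the cause was not tested.

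Of 28 lists, camera called 20 with its preset correlation, 0 with an estimated correlation, 11 with the acinar covariate and 12 with the myeloid covariate, and fry called 8. With an estimated correlation the β cell identity median stayed at −0.47 (adjusted p = 0.276) and the proliferation median at 1.55 (adjusted p = 0.353), because that setting changes only the test. Both lists were called by fry (adjusted p 0.0164 and 0.036). The others that fry called were exocytosis, genes normally low in β cells, delta, PP and epsilon cell, macrophage and myeloid, p53 target and lactogen response. Fry did not call the remaining lists that camera called with its preset correlation. With the acinar covariate the medians turned to −0.0289 for acinar genes, by construction, −0.0214 for ribosomal proteins, −0.0095 for translation factors and −0.0364 for glycolysis, which was −0.0336 with no filter. With the myeloid covariate they turned to −0.0145 for myeloid genes, by construction, −0.49 for lymphocyte genes, −0.34 for interferon genes and 0.0362 for autophagy. Over left-out libraries the medians ranged from −0.0141 to 0.14 for polyamine genes, −0.0176 to 0.0908 for fatty acid genes and −0.0161 to 0.0337 for glycolysis, and the difference in the share of counts of hormone genes (knockout minus control) from −2.47 to 1.01 percentage points; the cause was not tested. The acinar share difference of 2.75 points ranged from 2.34 to 2.96. Depth and 3 libraries per group limit small changes: the simulated test recovered 36% of genes changed 1.5-fold.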

Other observations

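The tests of the share of β cells, of mast cells and of the complement, receptor and endothelial activation lists were chosen only after the values were seen, as were the 2 covariates, the tests with a covariate or a left-out library and an estimated correlation, and the proliferation score without knockout-labelled replicate 2. Complement genes were higher in the knockout-labelled libraries: 10 of 19 rose and 0 fell (16 rose adjusted over the list alone), among them C3 (2.23), C4b (2.11), Cfb (1.56) and C1qc (1.10). The median log2 fold change was 1.02 (camera p = 2.21e-11, p = 0.00315 with an estimated correlation). Genes of endothelial activation rose for 8 of 14, with 0 falling (10 rose adjusted over the list alone), including the adhesion molecules Sele (2.55), Selp (2.42), Vcam1 (1.90) and Icam1 (1.29). Their median was 1.51 (camera p = 3.22e-09, p = 0.0387 with an estimated correlation). Among 26 hormone and nutrient receptor genes, 10 fell and 1 rose (12 fell and 5 rose adjusted over the list alone). The incretin receptors Glp1r (−0.88) and Gipr (−0.94), the fatty acid receptor Ffar1 (−0.99) and Insrr (−0.88) fell, while the cholecystokinin receptor Cckar rose (2.41), with a median of −0.27 (camera p = 0.0173, p = 0.095 with an estimated correlation). Macrophage, stromal and endothelial markers were higher in the same libraries, C1qa, C1qb and C1qc also stand in the macrophage list, and Ccl2 and Cxcl1 in the interferon list, so these rises are not separate findings. These lists were drawn from values already seen, so their p-values describe them and do not test them independently.

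The lower β cell identity genes may reflect a change in β cells, a smaller share of β cells or other tissue in the preparation. Relative to the mean of Ins1, Ins2 and Iapp, the median change of the other members was −0.605 ± 0.231 (SE, 3 libraries per group). This comparison was chosen after the list was seen to be lower and the insulin transcripts were not. It describes those values and does not decide on a lower share of β cells alone. With the acinar score as a covariate the median was −0.377 (camera p = 2.63e-07, or p = 0.0363 with an estimated correlation, adjusted p = 0.385). That score did not overlap between the groups (3.88 to 7.22 in the controls, 8.36 to 8.56 in the knockout-labelled libraries). The fit therefore cannot separate acinar carry-over from the label. No single member was still called with that covariate, where the median SE over the 26 genes was 0.22 against 0.16. A genotype effect stays open as a hypothesis, as do the sex, age and diet of the mice and Cre in the controls, which were not given; Dhps was not called different.

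The rise of Tph1, with 537, 120 and 226 counts against 5, 0 and 1, may come from lactogen or growth hormone signalling, which induces Tph1 in β cells, including through a growth hormone sequence carried by some Cre transgenes. The other 12 members of the response list gave a camera p of 0.112 with a median of 0.215, so this test does not decide on that source. Counting Tph1, 10 of the 13 members had a positive log2 fold change and 3 a negative one. Mast cells also express Tph1. Counts of 7 abundant mast cell genes (5, 0 and 0 in the knockout-labelled libraries) summed to at most 0.93% of the Tph1 count there, which argues against mast cells. Whether this transgene carries that sequence is not given in the sources used here.

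The higher proliferation genes may stem from β cells or from other dividing cells in the preparation, and the list was not called with an estimated correlation (adjusted p = 0.353). Without knockout-labelled replicate 2, which had the highest lymphocyte score, the median was 1.482. The proliferation score of the other 2 knockout-labelled libraries exceeded the controls by 1.44 ± 0.38 (SE). That library alone therefore did not carry the rise, although without it the list was not called with an estimated correlation (adjusted p = 0.54). Lymphocytes as a source stay open, because knockout-labelled replicate 3 scored 0.72 on their list and the highest control −0.03. The median was 0.979 with the acinar covariate and 1.488 with the myeloid covariate (camera adjusted p = 3.79e-12 and 2.29e-05), but with an estimated correlation the adjusted p was 0.436 and 0.678. The bound set before these tests were run assumed a correlation of 0.01 while the estimate was 0.555. The acinar scores (3.88 to 7.22 in the controls, 8.36 to 8.56 in the knockout-labelled libraries) did not overlap between the groups. Nor did the myeloid scores (3.97 to 4.11 and 4.64 to 5.19). Acinar carry-over and myeloid cells therefore cannot be told apart from a change in β cells. Neither covariate left any of the 36 genes called (median SE 0.40, then 0.60 and 1.06), and stellate and endothelial cells were not tested as sources.

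The 6 libraries make 10 splits of 3 against 3, 1 of which, the real one, called 929 genes, and the highest of the others called 0; these splits are too few for a share under 0.05.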
